A study of Mus musculus with 5 samples.

How the data were processed

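The data were single-cell RNA profiles of newborn mouse skin cells made with the 3' droplet kit of 10x Genomics, 1 library for each of 5 time points (days 0, 1, 2, 3 and 4). Per the labels' protocols, skin was digested with collagenase and the suspension was sorted to leave out debris and doublets. The series' design text adds that the cells lacked CD73 and were treated with small molecules, whose names and doses are not given in the sources used here. Reads were counted by the authors with Cell Ranger (4.0.0 per the matrix header, 3.0.2 per the submitters' processing notes) on mm10 and handled in Seurat 3.2.3, per the submitters' processing notes; the filters and the clustering settings were not given in the sources used here. The deposited values were raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization. A matrix of all barcodes held 31053 genes, and a table of the annotated cells held 25322 of them; the totals of all annotated cells were the same in both, with 0 exceptions. Another kind of file gave the authors' cell type name of each annotated cell, which was used as it stood.

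Annotated cells numbered 5882, 8350, 8748, 9155 and 8402 on days 0 to 4, out of 7201, 18251, 13594, 14132 and 12586 barcodes, or 81.7, 45.8, 64.4, 64.8 and 66.8% of them. No further filter was set: the annotated cell with the fewest UMIs had 3261 on day 0, 4617 on day 1, 8144 on day 2, 8576 on day 3 and 3587 on day 4, and mitochondrial genes took at most 7.37, 5.80, 6.61, 8.30 and 8.46% of the UMIs of any annotated cell. Per the labels, doublets had been left out by the sort. Scrublet with an expected rate of 6% marked 0.119, 0.0479, 0.869, 1.25 and 2.33% of the annotated cells; whether the low rates of days 0 and 1 came from its automatic threshold or from few doublets was not tested, and removal of the 6% of cells with the highest score was added after the data were examined. Cells were kept as annotated in the main values.

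UMIs were summed over all annotated cells of a library, over its melanocytes and over its skeletal muscle classes, and expressed as UMIs per 1e6 of the sum (CPM). The skeletal muscle classes were the cells named muscle stem cells on day 0, Myod1+ cells on days 1 to 3, and immature, intermediate and mature myocytes on day 4. Each later day was set against day 0, muscle cells were set against melanocytes of the same library as a check of the annotation, and the intermediate and mature myocytes of day 4 were set against the immature ones. With 1 library per day no test was made: a CPM ratio has an exact conditional binomial 95% interval, a share has an exact Clopper-Pearson 95% interval, and both cover counting error only, not the spread between animals or cultures. A sum with fewer than 3 UMIs was set to a floor of 3 UMIs in a ratio. A gene was measured with at least 20 UMIs over the 2 sums, and it was called at least 2-fold higher or lower where its ratio was 2 or more, or 0.5 or less, with an interval that left out 1; these counts describe the libraries and are no test.

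Gene lists were fixed before the data were examined, as were the comparisons, the size rule, the rule for the genes named and 23 alternatives. The 17 marker lists stood for melanocytes, Schwann cells, muscle progenitors, differentiated skeletal muscle, fibroblasts, pericytes and smooth muscle, vascular endothelium, lymphatic endothelium, keratinocytes, macrophages, neutrophils, mast cells, T or NK cells, adipocytes, chondrocytes, erythroid cells and neurons. The 21 process lists held neural crest and melanoblast regulators, S phase, G2/M phase, immediate early response, TGF-beta targets, BMP targets, cAMP and CREB targets, retinoic acid targets, Wnt targets, Notch targets, p53 targets, hypoxia, glycolysis, oxidative phosphorylation, cholesterol synthesis, the integrated stress response, the unfolded protein response, interferon response, extracellular matrix, chemokines and inflammation, and the oxidative stress response. A few genes stand in more than 1 list, such as Mitf and Sox10 (melanocyte and neural crest), Col3a1 (fibroblast and extracellular matrix), Heyl (muscle progenitor and Notch) and Nr4a1 (immediate early and cAMP). The value of a list is the median log2 ratio of its measured members with an order-statistic 95% interval, beside its percentile among 10000 random lists of the same size matched on mean expression in 20 bins; lists with fewer than 3 measured members have no value.

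Genes named in the text are, for the last day of each main comparison and for mature against immature myocytes, the 12 with the highest lower bound and the 12 with the lowest upper bound of the ratio among genes of at least 50 CPM in the higher sum, without mitochondrial, ribosomal protein, haemoglobin and predicted genes and pseudogenes. They are joined by the 2 members of each list with the most CPM, the members with the highest and the lowest ratio, and Nt5e, Mitf, Dct, Pmel, Sox10, Pax7, Myf5, Myod1 and Myog. Some genes that meet this rule are not reported here. The mature myocyte comparison was added once the annotation had been read. Symbols came from the matrix, and a symbol held by 2 gene identifiers is printed with its identifier. Gene positions are those of GENCODE M21 on GRCm38 (mm10).

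To compare shares of cells across days of unlike depth, each annotated cell was thinned to 1000 UMIs without replacement, and a cell counted as positive with at least 2 UMIs of a list; all annotated cells had enough UMIs. Background from free RNA was read in endothelial and immune cells of the same library: the annotated endothelial cells on day 0, and on days 1 to 4 the clusters of the authors' other cells that were named by the vascular endothelium or macrophage list under the rules below. Macrophage clusters were named on days 2 and 3 only. Those clusters came from the 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.6. A cluster was named from at least 3 markers of a list that were 3-fold higher and present in 25% of its cells. It stayed unnamed if another list had as many such markers or had more members among the cluster's 10 top genes. It also stayed unnamed with none of its list among those genes and a median depth more than 3-fold below the library's. By these rules a day 1 cluster of 269 cells with 10 of 10 macrophage markers stayed unnamed. So did a day 4 cluster of 132 cells with 8 of 8 vascular endothelium markers. Unnamed clusters held 49.1, 13.2, 19.8 and 1.92% of the annotated cells on days 1 to 4. Clusters served only to find background cells, and mast cells and the myeloid cells of day 0 were left out of the background after a first look, since mast cells express Kit. The share of cells positive for both the melanocyte and the differentiated muscle list was set beside the share expected of independent lists and beside 20000 random pairs of cells of the library, thinned in the same way.

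The computation was tested on simulated Poisson counts drawn from the real sums, with 200 genes of at least 50 CPM changed by known folds. Such counts hold no spread between cells, animals or cultures, and finding changes in genes of lower CPM was not tested. For all annotated cells on day 4, melanocytes on day 3 and muscle cells on day 4, the intervals held the true ratio for 95.5, 96.0 and 96.0% of 17984, 10656 and 15130 genes. The size rule found 100, 98 and 100% of the 50 genes changed by 2.5-fold and 0% of the 50 changed by 1.5-fold in each comparison, and it called 0.360, 0.947 and 0.382% of the 17784, 10456 and 14930 unchanged genes. Alternatives were TMM factors from edgeR 4.0.16, totals without mitochondrial, ribosomal protein and haemoglobin genes, the mean of single-cell CPM, no minimum of UMIs, all barcodes, removal of doublets, other thinning depths and minimums, and the ones added later. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3. Barcodes outside the annotation entered only the alternative with all barcodes and the count of day 4 barcodes at the melanocyte level.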

Results

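Newborn mouse skin cells were profiled one cell at a time by counting UMIs per gene, in 5 libraries taken on days 0, 1, 2, 3 and 4 of a treatment with small molecules. The study's title names its aim, a chemical conversion of melanocytes, the pigment cells of skin, into skeletal muscle. Each day had 1 library, so values are given without a test. Intervals of ratios and shares cover counting error only, and those of list medians cover the spread of the list members. Annotated cells numbered 5882, 8350, 8748, 9155 and 8402 on days 0 to 4, with 135715786, 302347981, 601806745, 503634600 and 256311069 UMIs in all. The libraries had a median of 18866, 30519.5, 64652, 52157 and 28569 UMIs per cell. Cell type names are the authors' own. They named the skeletal muscle cells differently by day: muscle stem cells on day 0, Myod1+ cells on days 1 to 3, and immature, intermediate and mature myocytes on day 4. A change of cell handling, from fresh skin on day 0 to treated cells afterwards, goes together with every comparison against day 0. Nt5e, which encodes the CD73 that the profiled cells were selected to lack, stood at 2.52 CPM over all annotated cells on day 0 and at 0.168 CPM on day 4.

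The genes at the centre of the comparisons are protein coding and lie, on mm10, at these places: the melanocyte genes Dct on chromosome 14 (118012790 to 118052244), Pmel on chromosome 10 (128704195 to 128720238), Mitf on chromosome 6 (97807052 to 98021349) and Sox10 on chromosome 15 (79154908 to 79165240). Of the muscle genes, Pax7 lies on chromosome 4 (139737062 to 139833528), Myf5 on chromosome 10 (107482908 to 107486134), Myod1 on chromosome 7 (46376474 to 46379099) and Myog on chromosome 1 (134289989 to 134292548).

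The makeup of the libraries was compared to ask how cell types were spread over the treatment. Skeletal muscle classes made up 12.9% of the annotated cells on day 0 (759 cells, 95% interval 12.1 to 13.8%), 15.3% on day 1 (1280 cells, 14.6 to 16.1%) and 20.5% on day 2 (1789 cells, 19.6 to 21.3%). They made up 43.6% on day 3 (3989 cells, 42.6 to 44.6%) and 85.5% on day 4 (7182 cells, 84.7 to 86.2%). Melanocytes made up 1.14% on day 0 (67 cells, 0.884 to 1.44%), 2.30% on day 1 (192 cells, 1.99 to 2.64%), 2.93% on day 2 (256 cells, 2.58 to 3.30%) and 1.90% on day 3 (174 cells, 1.63 to 2.20%). No cell was named a melanocyte on day 4. The rest of the day 0 library was 45.5% stromal cells, 14.0% neurons or glia, 8.31% myeloid cells, 7.06% smooth muscle cells, 6.09 and 3.32% endothelial cells of 2 kinds, and 1.62% keratinocytes. On days 1 to 4 the authors pooled all remaining cells into 1 class, which held 82.4, 76.6, 54.5 and 14.5% of the cells. Of the day 4 cells, 65.7% were immature, 14.0% intermediate and 5.80% mature myocytes.

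**Figure D1:**
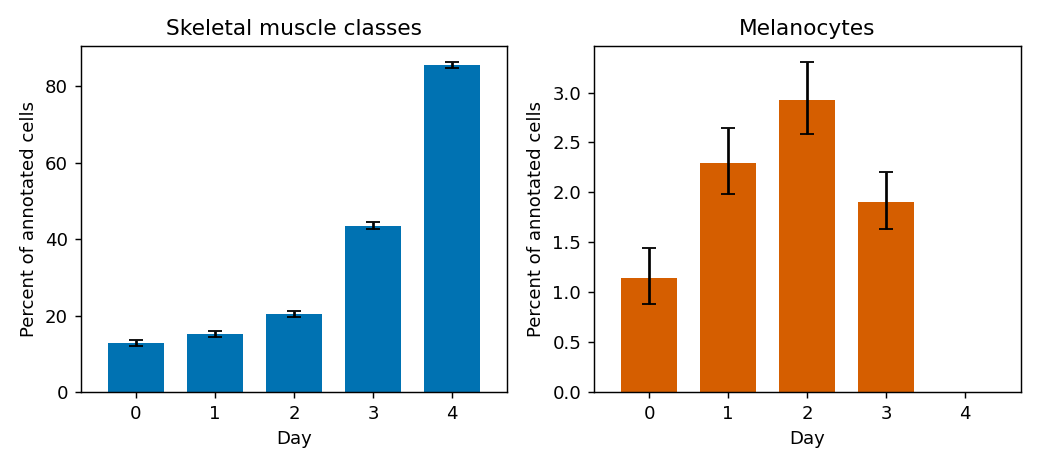
Share of annotated cells (percent) in the skeletal muscle classes (left) and named melanocytes (right) by day; bars are 1 library each, and error bars are exact 95% intervals of counting error. Muscle classes held 12.9% of the cells on day 0 and 85.5% on day 4, while melanocytes were between 1.14 and 2.93% up to day 3 and absent from the day 4 names.

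The same question was put without the cell type names, by counting marker UMIs in cells thinned to 1000 UMIs. Markers of differentiated skeletal muscle, such as the fusion, sarcomere and neuromuscular genes, were present with at least 2 UMIs in 4.42% of the cells on day 0 (3.91 to 4.98%), 0.479% on day 1 (0.342 to 0.652%) and 2.41% on day 2 (2.10 to 2.76%). The share was 17.5% on day 3 (16.7 to 18.3%) and 69.7% on day 4 (68.7 to 70.6%). Day 1 thus held fewer such cells than fresh skin, at 0.108 times the day 0 share (0.0757 to 0.152). The size of this drop depended on the setting, with 6.79 against 16.2% for at least 1 UMI, 0.0958 against 2.06% for at least 3 UMIs and 1.82 against 9.71% at 2000 UMIs. Day 4 held 15.8 times the day 0 share (13.9 to 17.9), or 3.98 on the log2 scale, which was 2.33 with at least 1 UMI and 4.88 with at least 3 UMIs. Background cells were taken as cells that do not form muscle, which was assumed and not tested. They were endothelial cells alone on days 0, 1 and 4. On days 2 and 3 they were endothelial cells with macrophages (147 of 327 and 80 of 104), so their makeup differed by day. They were positive in 1.27% of cases on day 0 (7 of 553), 0 of 292 on day 1 and 0.306% on day 2. They were positive in 6.73% on day 3 (7 of 104, 2.75 to 13.4%) and 23.9% on day 4 (84 of 352, 19.5 to 28.7%). Their median depths before thinning were 31446, 19468, 27311, 34609.5 and 42168 UMIs. On day 4 Scrublet marked 7.70% of the authors' other cells, which held these background cells, against 1.42% of the muscle classes. The median other cell of that day had 0.0191% of its UMIs in the differentiated list. The source of the 23.9%, such as free RNA or doublets, was not tested. Markers of muscle progenitors were seen in 4.20% of all cells on day 0, 3.93% on day 1, 6.82% on day 2, 11.9% on day 3 and 26.1% on day 4 (25.1 to 27.0%). Among the background cells these shares were 0.181, 0, 0, 0 and 3.13%. The melanocyte list was found in 2.07% of the cells on day 0, 2.55% on day 1, 3.25% on day 2 and 2.21% on day 3. On day 4 it was found in 4 of 8402 cells, or 0.0476% (0.0130 to 0.122%). No background cell had melanocyte markers on days 0, 3 and 4, the myeloid cells of day 0 being left out, and 0.342 and 0.612% of them had on days 1 and 2. Without thinning, 58.3, 48.8, 81.6, 99.9 and 99.3% of the cells on days 0 to 4 had at least 2 UMIs of differentiated muscle. These shares were 23.9, 23.6, 34.6, 84.4 and 90.5% for muscle progenitors, and 18.6, 30.6, 37.9, 29.0 and 1.04% for melanocytes.

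**Figure D2:**
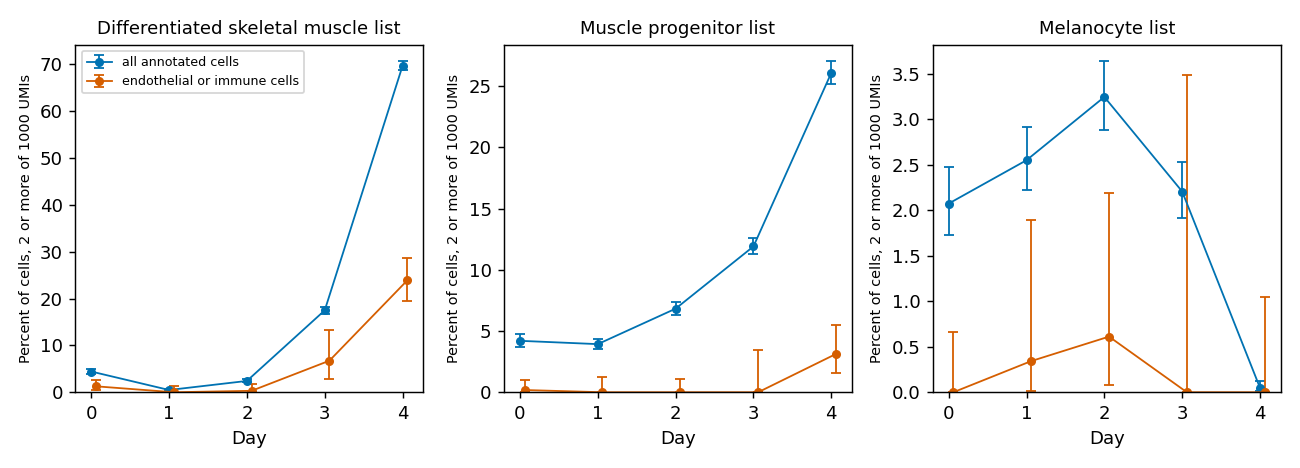
Share of cells (percent) with at least 2 marker UMIs after thinning to 1000 UMIs, by day, for all annotated cells and for background cells of the same library (endothelial, with macrophages on days 2 and 3); points are 1 library each, and error bars are exact 95% intervals. Differentiated muscle markers were in 69.7% of all cells and 23.9% of endothelial cells on day 4, and melanocyte markers were in 0.0476% of all cells on that day.

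Cells with melanocyte and muscle markers together would be sought in a direct conversion, so their share was set against chance. On day 3 both lists were positive in 17 of 9155 cells, or 0.186% (0.108 to 0.297%). This was fewer than the 35.3 cells, or 0.386%, expected of independent lists, and random cell pairs gave 0.61% (0.507 to 0.728%). Random pairs stand for a library of doublets alone, so a share below theirs does not speak against doublets. Independence ignores that each cell has 1 type, so a shortfall from it does not speak against conversion either. The other days had 5 such cells on day 0 (5.39 expected), 2 on day 1 (1.02 expected), 9 on day 2 (6.85 expected) and 2 on day 4 (2.79 expected). With 2000 UMIs per cell, day 3 had 60 cells against 72.8 expected, 0.655% (up to 0.843%), a limit that lies above the expected 0.795% but below the 1.22% of pairs (1.07 to 1.38%). Day 2 had 10 against 18.5 expected. Day 1 had 18 against 4.93 expected, and 0.216% (0.128 to 0.340%) against 0.1% of pairs (0.0611 to 0.154%), intervals that overlap. Mef2c, which melanocytes make, gave 31 of the 41 muscle UMIs in those cells, of which 16 were named melanocytes.

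Over all annotated cells, day 4 was set against day 0 to ask which programs separated the treated cells from fresh skin. Muscle genes were higher and those of nearly all other skin cell types were lower on day 4. Of the differentiated skeletal muscle list, 20 of 25 measured members were at least 2-fold higher and 2 were lower (median log2 ratio 2.94, interval 2.06 to 4.05, percentile 100 among random lists). Ttn, the giant spring protein of the sarcomere, was at 1891 CPM on day 4 and 29.1 on day 0, a ratio of 65.1 (63.1 to 67.2), and Actc1, the actin of fetal muscle, at 1066 against 41.9 CPM (25.4, 24.8 to 26.1). Mymx, a peptide needed for myoblast fusion, was 31.4-fold higher (28.6 to 34.5), Chrng, the fetal subunit of the acetylcholine receptor, 54.4-fold (46.7 to 63.8), and Tnnt1, slow troponin T, 23.0-fold (22.3 to 23.9). Mef2c, a muscle regulator also made by other skin cells, was lower at 0.272 (0.264 to 0.280). The muscle ankyrin repeat genes Ankrd2 and Ankrd1 stood out at 99.1-fold (87.1 to 113) and 60.7-fold (56.1 to 65.8). Synpo2l, a Z-disc protein, was at 60.7-fold, Rbm24, a splicing regulator of muscle, at 28.4-fold and Eno3, the muscle enolase, at 24.0-fold. The hormone gene Sct was at 63.7-fold and Pnmal2 at 49.8-fold.

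Among muscle progenitor genes, 4 of 6 were at least 2-fold higher and 1 was lower on day 4 (median 2.01, -1.16 to 4.27, percentile 100). Cdh15, the M-cadherin of satellite cells, was at 350.3 CPM against 18.2 (19.3-fold), and Myod1, the regulator that commits cells to muscle, at 491 against 64.6 (7.60-fold, 7.44 to 7.77). Pax7, the mark of muscle stem cells, was at 43.7 against 5.50 (7.94-fold), Myf5, an early commitment factor, at 12.2 against 5.69 (2.14-fold). Msc, a repressor of differentiation, was lower at 0.447. Myog, which drives terminal differentiation, was at 455 against 29.5 CPM (15.4-fold, 14.9 to 15.9). All 12 melanocyte genes were at least 2-fold lower (median -5.78, -6.90 to -5.02, percentile 0). Dct, an enzyme of melanin synthesis, was at 1.58 against 86.6 CPM (0.0182, 0.0164 to 0.0201) and the melanosome protein gene Pmel at 0.0138. Mitf, the master regulator of pigment cells, was at 0.0964 and Sox10 at 0.0183. Tyr, which starts melanin synthesis, had 2 UMIs on day 4 and 3.61 CPM on day 0 (ratio interval 0.000261 to 0.00785). Neural crest and melanoblast regulators were lower in 10 of 12 members (median -3.51, -4.77 to -1.40), from Foxd3 at 0.0175 to Snai2, which was higher at 1.61.

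Markers of every other skin cell type were lower by median. Fibroblast genes were lower in 9 of 11 members (median -7.61), led by collagen III (Col3a1, 46.4 against 9892 CPM) and the matrix gene Dpt (0.00144), while Crabp1 was 2.53-fold higher. Schwann cell genes were lower in 10 of 10 (-6.18) and macrophage genes in 10 of 10 (-6.87, lysozyme gene Lyz2 at 0.00680). Lymphatic genes were lower in 5 of 5 (-6.67) and keratinocyte genes in 9 of 9 (-3.38, Krt14 of basal keratinocytes at 0.145). Ccl21a (ENSMUSG00000094686), the chemokine of lymphatic vessels, had 0 UMIs on day 4 and 1976 CPM on day 0, a ratio of at most 5.92e-06 against the floor of 3 UMIs. Pericyte and smooth muscle genes split, with 6 of 9 lower (-4.55, -9.27 to 0.23), from Rgs5 of pericytes at 0.000629 to smooth muscle actin Acta2, which was higher at 1.57. Of vascular endothelium 6 of 8 were lower (-2.45, Cldn5 of tight junctions at 0.0115), of mast cells 4 of 4 (-8.72), of neutrophils 4 of 4 (-5.79) and of erythroid cells 4 of 4 (-5.06). The same held for adipocytes in 5 of 5 (-4.60, Fabp4 at 0.00523), chondrocytes in 3 of 3 (-4.16) and T or NK cells in 5 of 6 (-4.78, with Trdc higher at 2.27). The neuron list had 3 of 6 lower and 1 higher (-0.90), namely Tubb3, a neuronal tubulin, at 89.4 against 4.04 CPM (22.1-fold, 20.3 to 24.1).

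Genes of the cell cycle were higher on day 4. Of the S phase list 17 of 20 were at least 2-fold higher (median 1.91, 1.70 to 2.43), among them Rrm2 of nucleotide synthesis at 6.28-fold. Of the G2/M list 19 of 20 were (2.79, 2.24 to 3.12), with the topoisomerase Top2a at 469.6 against 67.6 CPM (6.95-fold) and the mitotic kinase Plk1 at 14.3-fold. Glycolysis genes were higher in 9 of 12 (1.67, 0.81 to 2.56; Gapdh 6.17-fold and Pkm 6.05-fold) with Hk2 lower at 0.0747. Oxidative phosphorylation genes were higher in 11 of 15 (1.33, 0.82 to 1.67; Cyc1 4.73-fold). Extracellular matrix genes were lower in 15 of 15 (-4.81, -7.74 to -3.53), from the elastin gene Eln at 0.000252 to Tnc at 0.323. Interferon response genes were lower in 10 of 10 (-8.34, -10.48 to -3.68), with the antiviral Ifit1 at 0.0741 against 533 CPM. Ifnb1, interferon beta itself, had 0 UMIs on day 4 against 71.2 CPM. Chemokine and inflammation genes were lower in 9 of 10 (-5.98; Ccl2 33.7 against 6488 CPM and Cxcl1 44.2 against 3278). So were the chemokines Ccl4 (0.0234 against 959 CPM), Ccl3 (0.0585 against 219) and Ccl5 (0.0351 against 161). Further genes near the bottom were the antigen presentation gene Cd74, the antiviral Oasl1, and the matrix genes Clec3b and Aspn. Of the growth factor gene Csf2, 1 UMI was left (68.7 CPM on day 0; ratio interval 1.44e-06 to 0.000317).

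Immediate early genes, the fast response to stress and handling, were lower in 13 of 13 members (-5.49; Junb 35.5 against 1591 CPM). Targets of TGF-beta were lower in 8 of 8 (-4.51; Pmepa1 at 0.0149), of BMP in 5 of 8 (-3.12, with Id1 higher at 1.36), of cAMP and CREB in 7 of 12 (-1.64, with Ppargc1a higher at 3.75). They were lower for Wnt in 7 of 10 (-2.19, with Lgr5 higher at 5.21), Notch in 5 of 6 (-2.81; Hes1 at 0.0962) and retinoic acid in 6 of 9 (-1.80). Hypoxia genes were lower in 8 of 11 (-1.71). The unfolded protein response had 0 of 9 higher and 3 lower (-0.59). The remaining lists went both ways: p53 targets had 4 of 12 higher and 5 lower (-0.26; Bax 3.42-fold, Gdf15 0.0341), the integrated stress response 5 of 12 higher and 3 lower (0.42; Phgdh of serine synthesis 7.61-fold). Cholesterol synthesis had 1 of 14 higher and 5 lower (-0.58) and the oxidative stress response 2 of 9 higher and 2 lower (-0.46; G6pdx 6.06-fold, Hmox1 0.0553). The median over all 17983 measured genes was -0.48 log2, and TMM factors moved all values up by 0.46. The medians of p53 targets and of the oxidative stress response lay within that shift of 0. On day 3 in place of day 4, the keratinocyte and mast cell medians against day 0 were above 0, at 1.43 and 2.70.

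Within the annotated melanocytes, day 3, the last day on which any were named, was set against day 0 to ask what the treatment went along with in the starting cells. Pigment genes were lower as a list, though not each of them. Of the 12 melanocyte genes, 6 were at least 2-fold lower and 0 were higher (median -0.94, -1.69 to -0.38, percentile 0.06). The channel gene Trpm1 was at 39.5 against 479.5 CPM (0.0824, 0.0702 to 0.0962), Mitf at 174 against 562 (0.309, 0.281 to 0.340), the growth factor receptor Kit at 56.8 against 176 (0.322) and Pmel at 3513 against 7082 (0.496). In contrast, Dct was at 8283 against 7409.5 CPM (1.12, 1.09 to 1.14), Sox10 at 213 against 276 (0.771) and the pigment enzyme Tyrp1 at 3208 against 1923 (1.67, 1.60 to 1.74). Day 1 had 1 gene of this list lower and 1 higher (median -0.43), and day 2 had 3 lower (-0.74). The neural crest and melanoblast regulators were lower in 8 of 12 members on day 3 (-1.23, -1.69 to -0.67), with the endothelin receptor Ednrb of migrating melanoblasts at 89.1 against 738 CPM (0.121), Ets1 at 0.138 and Zeb2 at 0.467. Nt5e had 1 UMI in the melanocytes of day 0 and none on day 3.

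Cholesterol synthesis genes were higher in these cells on each day, in 6 of 14 members on day 1 (median 1.05), 12 of 14 on day 2 (1.79, 1.14 to 2.46) and 8 of 14 on day 3 (1.24, 0.57 to 1.69), all at percentile 100. Fdft1, which makes squalene, was at 45.3 against 8.27 CPM on day 3 (5.48-fold, 3.08 to 10.8), Fdps at 229.6 against 90.9 (2.52-fold, 2.11 to 3.04) and Hmgcs1 at 91.2 against 49.6 (1.84-fold). Cell cycle genes were highest on day 2, when 17 of 20 S phase members (1.51) and 18 of 20 G2/M members (1.79) were at least 2-fold higher, against 8 (0.89) and 14 (1.20) of 20 on day 3. Top2a was at 587 CPM on day 2 and 265 on day 3, against 121 on day 0. Interferon response genes were lower in 10 of 10 on day 3 (-6.00; Ifit1 0.940 against 216 CPM, Rsad2 0.752 against 205), extracellular matrix genes in 12 of 15 (-3.54; Col3a1 22.0 against 2583 CPM, while Fn1 was higher at 1.51). TGF-beta targets were lower in 7 of 7 (-3.10; Skil at 0.0516) and immediate early genes in 9 of 13 (-1.46; Fosb at 0.0360). Macrophage markers moved with these groups and were lower in 8 of 8 (-4.02; Fcer1g 2.26 against 82.7 CPM). Fibroblast markers were lower in 7 of 10 (-4.37) and Schwann cell markers in 6 of 8 (-1.69). Dlk1, of fetal mesenchyme and in none of the lists, was at 2.63 against 511 CPM. Genes with 0 UMIs on day 3 were Ccl21a, the matrix genes Mfap4, Clec3b, Aspn and Tnxb, the keratin Krt15 and the chemokine Ccl5, which had 172, 115, 111, 107, 51.0, 107 and 105 CPM on day 0, and Mfap5 was at 0.00572. Over all day 0 cells Ccl21a was at 1976, Aspn at 510 and Clec3b at 424 CPM, above their levels in melanocytes. Whether the falls of matrix, interferon and other cell type genes were of melanocyte RNA or of free RNA was not tested.

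Muscle transcripts were among the genes with the largest ratios in cells named melanocytes. On day 3, 19 of 20 measured members of the differentiated muscle list were at least 2-fold higher than on day 0 and 1 was lower (2.24, 1.90 to 3.03, percentile 100). The medians were 0.36 on day 1 and 0.62 on day 2, the latter -0.40 with no minimum of UMIs. Actc1 was at 88.2 against 2.07 CPM (42.7, 14.5 to 208), Des, the intermediate filament of muscle, at 119 against 3.45 (34.6, 14.7 to 107). Myod1 was at 89.0 and Myog at 55.7 CPM, each against 1 UMI (0.689 CPM; ratio intervals 23.1 to 5110.1 and 14.4 to 3202). Cdh15 and Ankrd1 had no UMI on day 0 and 117 and 97.0 CPM on day 3, at least 56.5-fold and 46.9-fold higher against the floor of 3 UMIs. Ankrd1 was not among the 19 muscle genes later set against background cells, so its background level was not compared. Levels in the Myod1+ cells of the same library were higher: 707 CPM of Actc1, 815 of Des, 640.2 of Myod1, 552 of Myog and 308 of Cdh15. The endothelial cells and macrophages of that library also held more than the melanocytes of Actc1 (139 CPM), Des (150), Myod1 (122) and Myog (145), but not of Cdh15 (55.4), so these UMIs alone do not show expression in melanocytes. Genes of other cell types stood beside them, with the wound keratin Krt6a at 135 CPM against 1 UMI, and Krt14 at 191 against 25.5 (7.50-fold). Crabp1 was at 90.6 against 0 UMIs (at least 43.9-fold against the floor), the chemokine Cxcl5 at 37.3-fold (14.5 to 137) and smooth muscle actin Acta2 at 5.73-fold. Over all cells of day 3, Krt14 was at 762 and Krt6a at 391 CPM. Tubb3 was at 223 against 6.20 CPM (36.0-fold, 18.9 to 78.9), above the 65.2 CPM of all cells on day 3, Timp1 at 246 against 22.0 (11.2-fold) and Ctla2a at 83.5 against 2 UMIs (interval 16.7 to 502).

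The remaining lists in melanocytes on day 3 had fewer members past 2-fold or went both ways. Muscle progenitor genes had 2 of 4 higher and 2 lower (1.78), glycolysis 2 of 12 higher (0.90; Pgk1 3.15-fold), oxidative phosphorylation 0 of 15 either way (0.45), the unfolded protein response 2 of 9 higher and 1 lower (0.71; Sdf2l1 3.04-fold). The integrated stress response had 4 of 10 higher and 2 lower (-0.07; Psat1 3.37-fold), the oxidative stress response 3 of 8 higher and 1 lower (-0.49; Nqo1 4.71-fold). Retinoic acid targets had 2 of 5 higher and 2 lower (0.68; Dhrs3 6.06-fold) and BMP targets 1 of 6 higher and 5 lower (-1.77; Id1 6.60-fold, Id3 0.320). Chemokine genes were lower in 7 of 10 and higher in 1 (-1.68), p53 targets lower in 4 of 11 and higher in 2 (-0.52), and hypoxia genes lower in 3 of 8 (-0.75). The cAMP and CREB targets were lower in 5 of 12 and higher in 1 (-0.88), Notch targets lower in 2 of 4 and higher in 1 (-0.70), and Wnt targets lower in 2 of 5 with a median of -0.16 that was 0.0177 with TMM factors. Keratinocyte genes had 3 of 8 higher and 2 lower (0.83). Only 67 cells and 1451374 UMIs stood behind the melanocyte values of day 0, against 174 cells and 5317259 UMIs on day 3, and the median of all 10644 measured genes was -0.13 log2.

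**Figure D3:**
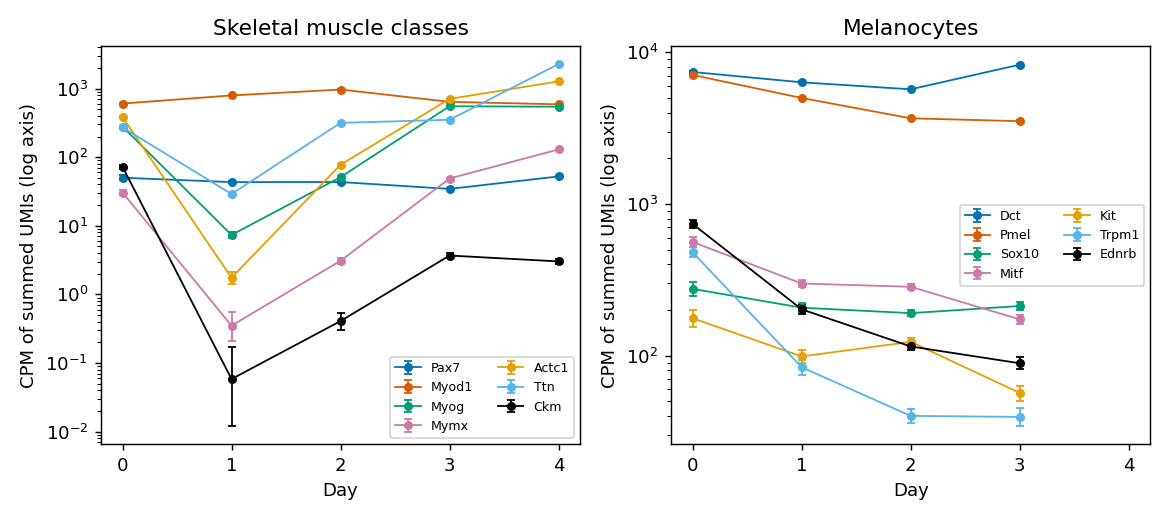
CPM of summed UMIs (log axis) by day in the skeletal muscle classes (left) and in cells named melanocytes (right), 1 library per day, with exact 95% intervals of counting error. In muscle cells Actc1 was at 384 CPM on day 0, 1.75 on day 1 and 1271 on day 4. Myod1, which names the class on days 1 to 3, lay between 589 and 968. In melanocytes Dct was at 8283 CPM on day 3 while Trpm1 was at 39.5.

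Within the skeletal muscle classes, each later day was set against the muscle stem cells of day 0, to ask how the muscle cells of the treatment differed from those of fresh skin. Of the differentiated list, 24 of 25 were at least 2-fold lower on day 1 (median -5.93, -7.34 to -5.25, percentile 0), 23 on day 2 (-2.52) and 10 on day 3 with 2 higher (-0.79, -1.64 to -0.23). On day 4, 9 were higher and 6 lower (0.04, percentile 48.9). The day 0 class, labelled PC muscle MuSC, had 127 of 759 cells (16.7%) with at least 2 UMIs of this list after thinning to 1000. On day 1 this held for 8 of 1280 cells (0.625%). Whether the sums fell through fewer such cells or through lower levels in each was not tested. Actc1 was at 384 CPM on day 0 and at 1.75, 77.4, 707 and 1271 on days 1 to 4, Ttn at 272 and then 29.0, 316, 351 and 2269.9, and Myog at 279 and then 7.35, 51.1, 552 and 544. Acta1, skeletal actin, was lower on day 4, at 190.2 against 798 CPM on day 0 (0.238), as was Ckm, muscle creatine kinase, at 3.02 against 72.7 (0.0416, 0.0376 to 0.0460). Myod1 stayed between 589 and 968 CPM on all days, with a day 4 ratio of 0.974. The class of days 1 to 3 is named for Myod1, so its level there may follow from the naming. Pax7 stayed between 34.5 and 52.4 CPM, while Myf5 was at 52.6, 64.7, 48.3, 20.5 and 14.6 CPM on days 0 to 4. The progenitor list had 3 of 6 members lower on day 1 (-1.14), and 1 higher and 3 lower on day 4 (-0.66), with Cdh15 at 2.55-fold and Msc at 0.0690.

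Day 4 muscle cells were higher than day 0 muscle cells in glycolysis and mitosis genes. Glycolysis genes were at least 2-fold higher in 4, 8, 8 and 10 of 12 members on days 1 to 4 (medians 0.90, 1.23, 1.37 and 1.43), with Gapdh at 5732 against 1753 CPM on day 4 (3.27-fold, 3.23 to 3.31). Aldoa (ENSMUSG00000030695) was at 3.98-fold and Pkm at 2.94-fold, while Hk2 was lower at 0.264. G2/M genes were higher in 13 of 20 on day 4 (1.29, 0.83 to 2.11; Plk1 7.37-fold, Top2a 2.12-fold), S phase genes in 6 of 20 (0.68; Uhrf1 2.55-fold) and oxidative phosphorylation genes in 6 of 15 (0.81; Cyc1 3.12-fold). On day 1 the integrated stress response was higher in 7 of 12 members (1.24) and the oxidative stress response in 6 of 9 (1.42, percentile 100). Among the named genes stood Shmt2 of one-carbon metabolism (4.66-fold, 4.25 to 5.12), the detoxifying enzyme Nqo1 (9.35-fold) and G6pdx of the pentose phosphate path (8.96-fold). On day 4 these lists had 4 higher and 3 lower (-0.38) and 3 higher and 2 lower (-0.12). The genes with the highest day 4 ratios were Tubb3 (97.4 against 1.31 CPM, 74.5-fold, 47.1 to 126), Sct (49.2-fold), Ankrd2 (34.2-fold), and the galectin Lgals3 (1119.9 against 41.3 CPM, 27.1-fold). They were followed by Anxa3 (21.7-fold), Tspan9 (15.5-fold), Ass1 of arginine synthesis (14.6-fold), Ldhb (14.4-fold), the histone Hist2h2ac (14.3-fold), Smyd1, a methyltransferase of sarcomere assembly (12.5-fold), Got1 (11.0-fold) and Ankrd1 (10.5-fold).

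Matrix, signalling and inflammation genes were lower in the day 4 muscle cells. Extracellular matrix genes were lower in 13 of 15 (-5.60, -7.35 to -2.27), with the collagen gene Col1a1 at 0.00307. Col15a1, Mfap5, Dpt and the hyaluronan-binding Tnfaip6 were at 0.00110, 0.000788, 0.000223 and 0.000754. Dlk1 was at 2.87 against 1899 CPM (0.00151), Chodl at 0.00106 and Serping1 at 0.00264. Interferon response genes were lower in 10 of 10 (-5.26; Ifit1 0 UMIs against 22.9 CPM) and chemokine genes in 8 of 10 (-6.08; Ccl2 2.53 against 849 CPM, Cxcl2 at 0.00156) with Ccl5 and Cxcl10 at 0.000403 and 0.00150. Immediate early genes were lower in 11 of 13 (-4.14, with Jun higher at 1.32), TGF-beta targets in 7 of 8 (-4.70; Ctgf at 0.00329), hypoxia genes in 6 of 11 (-1.73; Adm at 0.0252) and Notch targets in 3 of 5 (-1.29; Hes1 at 0.372). Of signalling lists, BMP targets were lower in 4 of 7 (-2.05), Wnt targets in 4 of 7 with 1 higher (-1.89; Lgr5 6.43-fold). The cAMP and CREB targets were lower in 5 of 12 with 2 higher (-0.98; Ppargc1a 7.51-fold), and retinoic acid targets in 2 of 8 with 1 higher (-0.01). Cholesterol synthesis (2 of 14 higher, 2 lower, -0.23) and p53 targets (3 of 12 higher, 3 lower, -0.23; Bax 4.85-fold) went both ways, the unfolded protein response had 0 of 9 higher and 3 lower (-0.03), and the TMM shift of 0.26 would move these 3 medians past 0. Macrophage markers were lower in 8 of 9 members as well (-2.93) and fibroblast markers in 10 of 11 (-5.66). Free RNA of other day 0 cells was not tested as a source of these falls or of those in matrix, interferon and chemokine genes. Keratinocyte markers were higher in 5 of 8 on day 3 (1.78; Krt14 112 CPM against 7.77 on day 0) and lower in 6 of 7 on day 4 (-2.06). Melanocyte genes were low, with Dct at 2.40 CPM on day 0 and 1.92 on day 4. Most of its day 4 UMIs lay in 3 cells named myocytes, which held 119, 122 and 110. The list median of -1.13 was 0.18 once the 6% of cells with the highest doublet score were removed. The class was named differently on each side of this comparison, and the median of all 15104 measured genes was -0.19 log2.

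**Figure D4:**
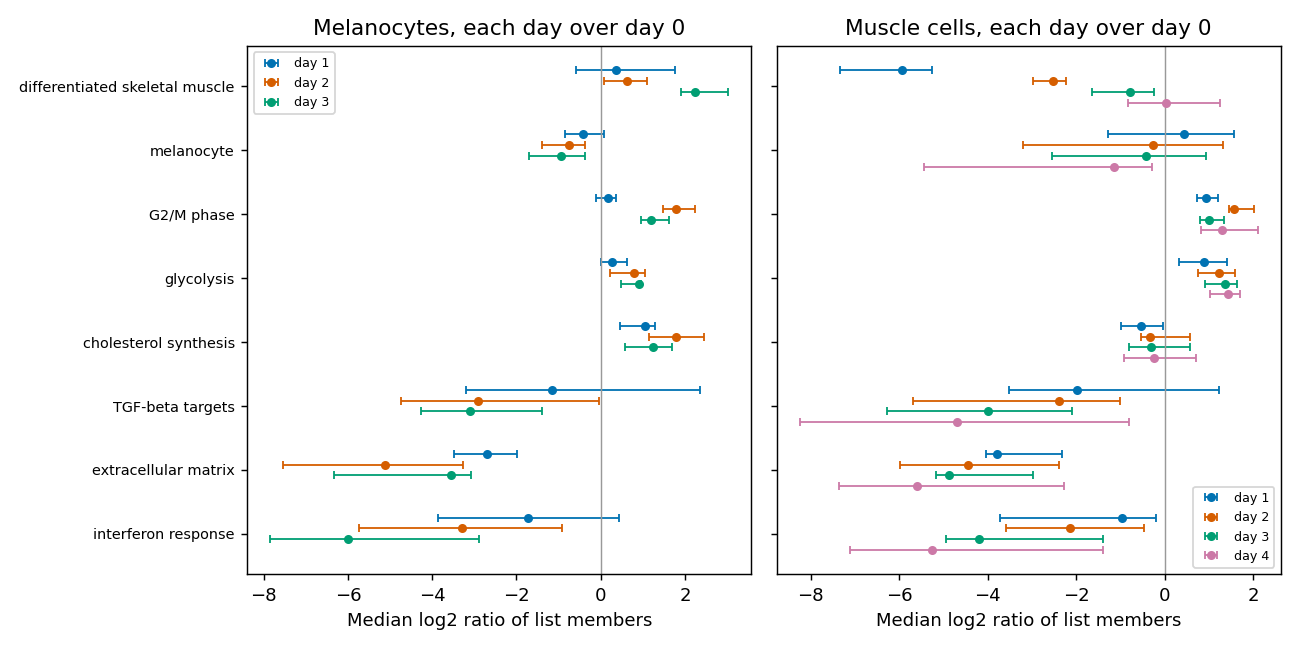
Median log2 ratio of list members, each later day over day 0, for cells named melanocytes (left) and for the skeletal muscle classes (right); bars are order-statistic 95% intervals over list members, 1 library per day. The differentiated muscle median was 2.24 in melanocytes on day 3 and was -5.93 on day 1 and 0.04 on day 4 in muscle cells; cholesterol synthesis was at 1.24 in melanocytes on day 3 and -0.23 in muscle cells on day 4.

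Muscle cells set against melanocytes of the same library checked the annotation, since the names may rest on these very markers. All 12 melanocyte genes were at least 2-fold lower in the muscle cells on days 0 to 3 (medians -9.54, -9.98, -9.90 and -10.16). Differentiated muscle genes were higher in 24 of 25, 6 of 20, 23 of 25 and 24 of 25 members (5.52, 0.47, 3.36 and 2.59). Cholesterol synthesis genes differed as well and were lower in muscle cells in 2 of 14 members on day 0 (-0.06), 13 on day 1 (-1.57), 13 on day 2 (-2.09) and 12 on day 3 (-1.51).

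On day 4 the 3 myocyte stages were compared to ask what set the stages apart within 1 library. Mature myocytes were higher in contractile genes and lower in genes of division and of the stem cell state. All 25 differentiated muscle genes were at least 2-fold higher in mature than in immature myocytes (4.56, 3.24 to 5.32) and 23 of 25 in intermediate ones (2.49, 2.15 to 3.03), which checks the names. Acta1 was at 2429.5 against 18.7 CPM (130.2-fold, 125 to 135), embryonic myosin Myh3 at 1962 against 29.9 (65.6-fold) and perinatal myosin Myh8 at 63.6-fold. The light chain gene Myl1 was at 86.9-fold, the troponins Tnni1 and Tnnc1 at 62.4-fold and 46.1-fold, Ckm at 142-fold (105 to 196) and Actc1 at 9.42-fold. Outside the list, Lmod2 was at 119-fold and the myosin chaperone Unc45b at 104-fold. The calcium store protein Casq2 was at 89.7-fold, Myo18b at 86.8-fold and Filip1 at 55.9-fold. Myog was at 260, 1437 and 2083 CPM in immature, intermediate and mature myocytes, and Myod1 at 529, 854 and 725.

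S phase genes were lower in 20 of 20 members in mature against immature myocytes (-2.04, -2.43 to -1.84; Cdc6 at 0.0614) and in 9 of 20 in intermediate ones (-0.89). G2/M genes were lower in 18 of 20 (-1.83; Top2a 112 against 533 CPM) and 0 of 20 (-0.11). Replication-linked histones were among the lowest genes, with Hist1h1b at 0.0533, Hist1h2ap at 0.0701 and Hist1h2ae at 0.105, next to Fam111a, Hells, Fbxo5, Clspn, Aunip and Dtl, which act in DNA replication, repair or the cell cycle, at 0.0699 to 0.0998. Pax7 was at 62.9, 15.3 and 4.91 CPM in the 3 stages (mature against immature 0.0780, 0.0599 to 0.0999), and Myf5 at 17.7, 3.12 and 2.57. The Notch targets Hes1 and Heyl were at 0.0527 and 0.0623, and the membrane and cytoskeleton genes Cav1 and Tagln2 at 0.0942 and 0.102. Notch targets were lower in 4 of 5 (-3.20) and progenitor genes in 4 of 6 (-3.23), while Cdh15 was at 412 and 432 CPM in immature and mature cells. Glycolysis and oxidative phosphorylation genes had 0 of 12 and 0 of 15 members past 2-fold (-0.21 and 0.18), and extracellular matrix genes were lower in 9 of 14 (-1.12). Median depths were 28636, 24562 and 24410 UMIs in immature, intermediate and mature myocytes.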

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

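The test of free RNA was first set for days 2 and 3 together and was parted by day after its result was seen. The further conditions on the tests of doublets, of dilution and of myocytes with melanocyte transcripts, and the values of annotated cells and of RNA added by conversion, were also chosen after, and the depth of the picked cells was tested last; the other tests of this part were set before their results.

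Differentiated muscle genes stood apart between 2 cell classes under the same contrast, day 3 against day 0, with a median log2 ratio of 2.24 in cells named melanocytes and -0.79 in the skeletal muscle classes; the difference itself was not tested. Free RNA at 1 level in every droplet would put muscle genes in melanocytes at the level of endothelial and immune cells of the same library. Over 19 muscle genes the ratio of melanocytes to those cells was 3.84 on day 2 (2.52 to 5.02), which argues against free RNA alone. It was 0.728 on day 3 (0.555 to 0.829), so the melanocytes held less than those cells. That met the limit set for free RNA, which bounded the ratio only from above. The interval also lay below an equal level, so those cells are an uncertain measure of free RNA on day 3. Free RNA therefore stays open for that day. Without the 10% of cells of each class with the most muscle RNA, the ratio was 1.16 on day 3 (0.841 to 1.42) and 1.05 on day 2 (0.728 to 1.75). Those cells were picked by the value tested, and doublets cannot be told apart from a start of the muscle program in a few melanocytes. The picked cells had 0.994 times the median UMIs of the other melanocytes on day 2 (0.433 to 1.70) and 0.905 times on day 3 (0.412 to 1.93), while a melanocyte plus a Myod1+ cell would have 2.81 and 2.73 times. Both intervals lay below those values, but the bound of 1.5 set beforehand lay within both. Picking by the muscle share of a cell's own UMIs can also favour cells of low depth. The depth test therefore cannot decide on doublets.

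The absence of melanocytes from the day 4 names drew attention to barcodes outside the annotation: 10 of them reached the share of melanocyte UMIs that 95% of the day 3 melanocytes had, though each held only 5 to 18 melanocyte UMIs. With 3 annotated cells they made 13 such barcodes. Among the 3, 2 cells named immature myocytes had 119 and 110 UMIs of Dct and 0 of Myod1 and Myog, a melanocyte profile under another name. Whether further melanocytes were left out cannot be told apart from their absence, since the 10 had under 1000 UMIs each. Growth of the muscle cells alone would leave 41.1 melanocytes among the day 4 cells outside muscle by the day 3 share, and 16.0, 33.1 and 44.9 by the shares of days 0, 1 and 2. The 13 found (6.92 to 22.2) lie below 3 of these 4, among them the day 3 share named beforehand, and the 3 annotated ones (0.619 to 8.77) below all 4. The 4 expected values come from annotated cells, so the 3 are the like count, and the other 10 held fewer UMIs than any annotated day 4 cell. Dilution at any of these 4 shares would leave more than those 3. Both intervals held counting error alone, while these 4 values differ more than that between single libraries outside muscle. With 1 library per day, dilution together with such a spread stays open. In immature myocytes as a class, 59 melanocyte genes stood at 0.797 times the level of other cells (0.462 to 1.30), which met the limit set beforehand against conversion. That limit was too weak to count, since the 41.1 melanocytes converted with their transcripts kept would add only 0.108 times that level (0.0599 to 0.223). The third annotated cell, an intermediate myocyte, had 122 UMIs of Dct beside 38 of Myod1 and 43 of Myog, and with 1 such cell a doublet cannot be told apart from a myocyte that kept melanocyte transcripts. Loss of the melanocytes and a conversion that erased their transcripts were not tested.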

How the results depend on the processing

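Removal of the 6% of cells with the highest doublet score, removal of the 10% of melanocytes with the most muscle RNA, and day 3 in place of day 4 were chosen after the data were seen. The alternatives gave 5430 values of 1062 results. Of these, 4530 lay within the interval of the main value and 891 outside it, and 9 changed sign where that interval left out 0. A value that changed sign inside an interval that held 0 counts among the first. For list medians the interval covers the spread of the members and not counting error, and the numbers were 2522, 79 and 8 of 2609. The sign changed for mast cell genes over all cells on day 2 with all barcodes (3.17) and differentiated muscle genes in melanocytes on day 2 with no minimum of UMIs (-0.40, as genes with few UMIs then sit at the floor of both sums). It changed for Wnt targets in melanocytes on day 3 with TMM factors (0.0177) and for the melanocyte genes of intermediate against immature myocytes with the mean over cells (-0.0422). It also changed without the highest doublet scores for macrophage genes in melanocytes on day 2 (0.10), Lyz2 in melanocytes on day 3 (0.88) and melanocyte genes in muscle cells on day 4 (0.18). With day 3 in place of day 4 it changed for keratinocyte (1.43) and mast cell genes (2.70). The cause was not tested.

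Among the main answers, TMM factors gave 3.25 for G2/M genes over all cells on day 4. Removal of the highest doublet scores gave 1.89 for differentiated muscle genes in melanocytes on day 3 and a muscle share of 42.5% on day 3; Scrublet's own calls gave a muscle share of 86.3% on day 4. With day 3 in place of day 4 the medians were -1.03 for melanocyte and 1.13 for differentiated muscle genes. The log2 ratio of thinned shares, day 4 over day 0, was 2.13, 2.39 and 2.34 for muscle progenitors at 500 UMIs, at least 1 UMI and at least 3 UMIs. It was 4.60, 3.06, 2.33 and 4.88 for differentiated muscle at 500 UMIs, 2000 UMIs, at least 1 UMI and at least 3 UMIs. Cells with both lists on day 3 were 0.655% at 2000 UMIs, where independent lists give 0.795%, and 0.0437% with at least 3 UMIs. The cause of the other moves was not tested. A minimum of 1000 UMIs removed no cell and so says nothing. No paired analysis was possible because each day has 1 library and no value comes from a test. Depth limited melanocytes most, with 1451374 UMIs on day 0.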

Other observations

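Sytl2, the tests on Cdh15 and the test on genes higher in muscle stem cells were chosen after their results were seen, and a control that makes the first test of descent void was added after its result.

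Over all annotated cells, Krt14 and Krt6a were highest on day 2 and mast cell genes on day 3. With all barcodes the mast cell medians were 3.17 on day 2 and 3.12 on day 3, so the day 3 peak of mast cell genes held for the annotated cells only. Krt14 was at 169.9, 491, 2299, 762 and 24.7 CPM on days 0 to 4 and Krt6a, made in wounds, at 14.4, 410.0, 1665, 391 and 13.1, while Krt15 of resting basal cells was at 24.5, 1.57, 0.339, 1.39 and 0.00390. The keratinocyte median was 1.37 on day 1, 3.71 on day 2 and 1.43 on day 3. Mast cell genes were higher in 6 of 6 members on day 3 (median 2.70), with the proteases Cma1 at 71.9 and Tpsb2 at 34.8 CPM, against 9.84 and 4.10 on day 0 and at most 1 UMI each on day 4.

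Over all cells on day 1, 8 of 12 members of the integrated stress response (median 1.80) and 6 of 9 of the oxidative stress response were at least 2-fold higher than on day 0, with Nqo1 at 85.8 against 8.29 CPM and Psat1 at 180.1 against 40.6. In melanocytes the unfolded protein response was higher in 6 of 9 members on day 2 (1.44), with the chaperone Hspa5 at 1714 CPM on day 2 against 473 on day 0 and 779.9 on day 3, and Sdf2l1 at 254 against 66.1 CPM on day 0. Tubb3 was at 6.20, 61.6, 252 and 223 CPM in melanocytes on days 0 to 3 and at 1.31, 1.81, 19.3 and 94.5 in muscle cells on the same days.

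Cdh15 was singled out because its ratio of melanocytes to Myod1+ cells, less background, was above 100% of the other genes among 19 muscle genes on both days 2 and 3, so that rank is no test of its source. Sytl2, a gene that melanocytes also make, lay close to it (0.292 and 0.240 against 0.355 and 0.243). The other 17 genes had a median of 0.0490 and a highest value of 0.128 on day 2, and -0.0755 and -0.0180 on day 3. RNA of whole muscle cells would bring these genes along, which goes against it as the only source, but no test on a gene picked this way can settle it. After thinning to 2000 UMIs and without the 10% of cells with the most muscle RNA, Cdh15 was in 14.0% of melanocytes on day 3 (8.99 to 20.4%) against 10.6% of endothelial and immune cells (5.40 to 18.1%). On day 2 it was in 3.46% (1.51 to 6.71%) against 0 of 327 (up to 1.12%). Its making by melanocytes cannot be told apart from RNA of muscle cells, since the gene was picked by its ratio and the thinned shares overlap on day 3. Its CPM in melanocytes was 25.9 times that of the background cells on day 2 (17.2 to 40.9) and 2.11 times on day 3 (1.81 to 2.46).

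The Myod1+ cells of day 1 could come from the muscle stem cells of day 0 or from melanocytes. On genes at least 10-fold apart between the 2 day 0 classes, Myod1+ cells lay at 1.04 on a scale from melanocytes (0) to muscle stem cells (1) (0.951 to 1.11, 164 genes). Background cells lay at 0.662, so that value cannot be told apart from a mere lack of melanocyte genes. On the 50 genes higher in muscle stem cells they lay at 0.409 (0.261 to 0.633), above background cells at 0.0459 (-0.240 to 0.166) and melanocytes at 0.0829. Any cell with a muscle program would lie there, so descent from the stem cells cannot be told apart from another source by this value. For melanocytes in the middle of conversion, still holding their transcripts, 66 melanocyte genes in the Myod1+ cells stood at 0.426 times the background level (0.265 to 0.758). This met the limit set beforehand against them as the source of the class as a whole. Such cells may have been named melanocytes by those very genes, so the value cannot decide. Median depths were 38820.5 UMIs in the Myod1+ cells and 19468 in the background cells, and the ratio was not corrected for this gap. The share of Myod1+ cells on day 1 was 13.5 times the share of melanocytes on day 0 (10.1 to 18.2) and 1.19 times that of muscle stem cells; without a lineage mark, cells that had lost their melanocyte transcripts stay open.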
